A study of Mus musculus with 9 samples.

How the data were processed

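Bulk RNA sequencing was carried out on 9 tumours grown in C57BL/6J mice from MC38 cells, a mouse colorectal carcinoma line. The tumours were taken at day 21 after inoculation. Per the labels, 4 tumours came from vector control cells (Vec) and 5 from cells in which CD43 had been knocked out (CD43-KO), and each library came from the tumour tissue of a tumour-bearing mouse. Total RNA was extracted with TRIzol and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols. The labels gave no batch, date, sex or pairing, and replicates were numbered in the order of deposition within each group, so replicate numbers link no samples across groups.

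The authors deposited 1 table per library with whole-number counts per gene name, per the file headers and values, and these counts were not scaled to depth. The submitters' processing notes list HISAT2 2.1.0, StringTie 1.3.5 and DESeq2, and the build GRCm38, without a role or order. The counting step, the annotation, the strand setting and any filter are not given in the sources used here. All 9 tables held the same 42454 gene names in the same order, and 0 columns lacked a sample. Total counts ranged from 60751738 to 72114385 in Vec libraries and from 44814061 to 62194418 in CD43-KO libraries.

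Several features of the deposited counts limit what they can show. Of the names, 2346 carried a copy suffix, a number after a gene name. For 2341 of them the name without the suffix was also listed, and 1197 of these pairs had a mean count of at least 10 per library in either name. Summed counts of the pair lay within 10% of each other in 435 and differed more than 5-fold in 286, so the same reads may have been counted under more than 1 name in some of them. They held between 2.78% and 2.91% of the counts of a library. A gene with such a name is called uncertain below. A further 26 names had been turned into dates and were left without a gene name. In each library more names had a count of 2 than a count of 1, so the counts may not be counts of independent fragments. Mitochondrial messenger RNAs were not measured in these tables. Gene names were matched to the NCBI RefSeq table of GRCm38.p6, which gave coordinates for 85.1% of all names and 91.4% of the names tested. Without a stated strand setting, reads of a gene and of a gene on the opposite strand cannot be told apart.

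Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by filterByExpr on the group (minimum count 10, minimum total count 15), which left 18243 names, 1067 of them with a copy suffix. Libraries were scaled by TMM factors. The main test was edgeR's quasi-likelihood F test with robust estimation on a model with the group as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are CD43-KO over Vec, and their standard errors were taken as the log2 fold change divided by the square root of F. The prior degrees of freedom of the quasi-dispersion had a median of 3.41, beside 7 residual degrees of freedom, and the common biological coefficient of variation was 0.313. Levels are TMM-scaled CPM as returned by the cpm function of edgeR, given as mean ± SD over 4 Vec and 5 CD43-KO tumours. Exact tests and the SDs of levels and scores are over tumours. The SE of the chromosome 19 shift after a fit on GC content, gene length and level is from 1000 bootstrap draws over genes, which are not independent replicates. No pair of libraries agreed within sampling noise, as the lowest chi-square per degree of freedom over the 36 pairs was 35.5.

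A set of 33 gene lists was fixed for cell types, cell states, pathways, other tissues and RNA quality, of which 32 had measured members. Lists were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 32 lists. Camera with an estimated correlation and fry were run beside it. A list score is the mean log2 CPM of the measured members, expressed as the difference from the Vec mean, so it sums transcripts and is not a share of cells. Scores and single genes were also compared by a two-sided exact permutation test over all 126 splits of 9 tumours into 4 and 5, whose smallest possible p is 0.00794. The lists share 16 genes that stand in more than 1 list.

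Genes named in the text followed a rule. Spn, Cd274, Pdcd1, Cd8a, Cd4, Gzmb, Prf1 and Ifng were named in any case. In each direction, the 10 largest log2 fold changes were to be named among genes with an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the groups, followed by the 5 genes with the smallest p not already named, whether or not they passed. Predicted, clone-named and pseudogene names, and immunoglobulin and T cell receptor segments, were skipped. In each list described, up to 4 members that passed were to be named, or else the 2 most abundant members, as values. As no gene passed the main test, the rule on large changes was applied also to the genes called by DESeq2, a choice made after the values were seen. List members that passed when adjusted over the list alone, and some of those that DESeq2 called, were also named after their values were seen.

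The lists, the tests, the naming rule and most of the alternatives were fixed before the data were examined. The alternatives were RLE and upper quartile factors, no filter beyond 1 count, a stricter filter (a mean of 1 CPM in each group and 50 counts in 4 libraries), DESeq2, limma voom with sample quality weights, estimation without the robust option, a fold threshold of 1.5 by glmTreat, factors set without genes of the other-tissue lists, an estimated correlation, prior counts of 0.5 and 5, and leaving out each of the 9 tumours. Added after the data were seen were fits without the names with a copy suffix and fits with the mean log2 CPM of 4 Y-linked genes as a covariate. The count of DESeq2 calls was also rerun, without each tumour and without the names with a copy suffix.

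The scripts were tested on simulated counts for the 18243 names of the CD43-KO against Vec comparison, drawn from the means, library sizes and dispersions of these libraries with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were taken only from the more abundant names, so the recovery does not cover names with low counts. edgeR recovered 67 of the 100 with a 2-fold change and 89 of the 100 with a 4-fold change, with 3 false calls among 159. DESeq2 recovered 82 and 94 of 100, with 39 false calls among 215. Lists and chromosome 19 were tested on another set of counts. It had 1 coefficient of variation for all genes, not the dispersions of these tumours. There the camera test called 2 of 2 lists that had been changed and 0 others. A chromosome 19 shift set at -0.2 was found as -0.18. Simulated genes varied independently, while members of the real lists vary together (estimated correlation 0.88 in the T cell list). The 0 other calls thus do not show how often camera calls unchanged lists in these tumours.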

Results

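The study compared tumours formed in C57BL/6J mice by MC38 colorectal carcinoma cells that carried an empty vector (Vec, 4 tumours) or a knockout of CD43 (CD43-KO, 5 tumours). CD43, encoded by Spn, is a heavily sialylated membrane glycoprotein found mostly on leukocytes. Its knockout was made in the implanted cells, and the host mice were of the same strain in both groups. The title of the series frames the comparison as one of the immune response to colorectal cancer when CD43 is targeted. RNA of whole tumour tissue taken at day 21 was sequenced, so every value is a level in a mixture of carcinoma and host cells. Total counts were 63945523, 66734369, 72114385 and 60751738 in Vec replicates 1 to 4, and 61516319, 62194418, 44814061, 57489853 and 56536981 in CD43-KO replicates 1 to 5. CD43-KO replicate 3 thus had the lowest depth, and it also stood apart on the first principal component (34.9% of the variance), at 100.02 against a range of -45.6 to 51.2 in the other tumours.

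Spn transcripts were lower in every CD43-KO tumour than in any Vec tumour, but they were present in all of them. The gene (chromosome 7, 127123637 to 127145552, GRCm38) was at 45.8 ± 5.56 CPM (SD, n = 4) in Vec and 24.0 ± 10.5 CPM (SD, n = 5) in CD43-KO tumours. The Vec values were 41.0, 43.7, 44.6 and 53.8 CPM, and those of CD43-KO replicates 1 to 5 were 25.6, 33.6, 31.2, 22.97 and 6.81 CPM. The log2 fold change was -0.93 ± 0.36 (SE). A two-sided exact permutation test of the 9 values gave p = 0.0238, while the edgeR quasi-likelihood test did not pass over all genes (adjusted p = 0.280). The counts are per gene and cannot show a deletion inside it.

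Transcripts of the T cell coreceptors, of cytotoxic effectors and of the PD-1 checkpoint had higher means in CD43-KO tumours, with a wide spread between tumours, and none of these genes passed. Cd274, which encodes PD-L1, was at 28.3 ± 6.35 CPM in Vec and 60.9 ± 35.6 CPM in CD43-KO tumours (log2 fold change 1.10 ± 0.38 SE, edgeR adjusted p = 0.255). It passed only with DESeq2 (adjusted p = 0.0472). Pdcd1, which encodes PD-1, was at 6.03 ± 0.54 and 12.1 ± 7.01 CPM (log2 fold change 1.00 ± 0.39 SE, edgeR adjusted p = 0.283). Cd8a, a chain of the CD8 coreceptor, was at 10.6 ± 1.91 and 19.9 ± 11.8 CPM (0.90 ± 0.41 log2, edgeR adjusted p = 0.329), and Cd4, the coreceptor of helper T cells, at 2.09 ± 0.80 and 4.79 ± 2.79 CPM (1.20 ± 0.45 log2, edgeR adjusted p = 0.274). The cytotoxic granule genes Gzmb and Prf1 and the cytokine gene Ifng had log2 fold changes of 0.84 ± 0.60, 0.86 ± 0.64 and 1.15 ± 0.57, with edgeR adjusted p of 0.512, 0.530 and 0.360. For Gzmb and Prf1, CD43-KO replicates 4 and 5 lay below every Vec tumour while CD43-KO replicates 1 to 3 lay above every Vec tumour. Without CD43-KO replicate 3 the log2 fold changes were 0.34 for Gzmb, 0.25 for Prf1, 0.51 for Ifng, 0.70 for Cd274, 0.66 for Pdcd1 and 0.58 for Cd8a. Exact permutation p over these 7 genes ranged from 0.0635 for Cd274 to 0.738 for Prf1.

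**Figure D1:**
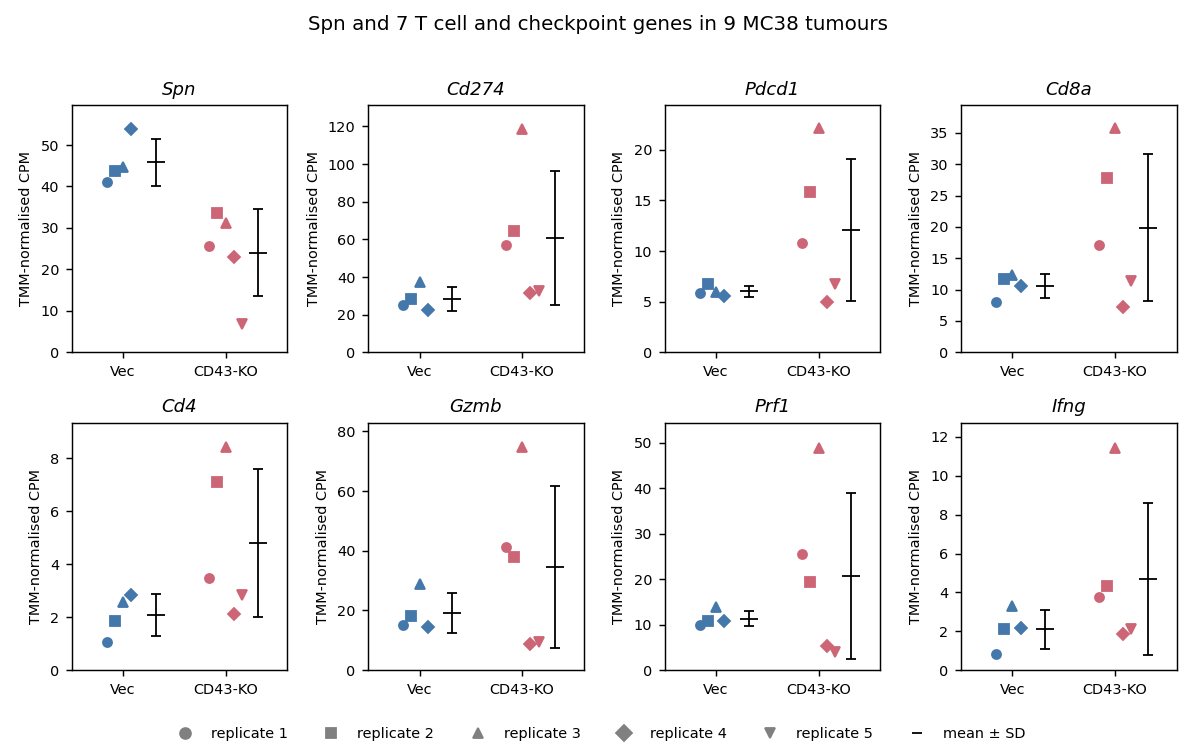
Levels of Spn, Cd274, Pdcd1, Cd8a, Cd4, Gzmb, Prf1 and Ifng (y axis, TMM-normalised CPM) in 4 Vec and 5 CD43-KO tumours, with a marker for each replicate and the group mean ± SD in black. Spn lay between 41.0 and 53.8 CPM in Vec tumours and between 6.81 and 33.6 CPM in CD43-KO tumours, and the other genes overlapped between the groups.

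Across the 18243 names tested, the edgeR quasi-likelihood test called 0 genes higher and 0 lower at an adjusted p of 0.05, with a smallest adjusted p of 0.0706. At an unadjusted p under 0.05 it gave 1414 higher and 1392 lower genes, where 912 in all would be met by chance. DESeq2 called 247 genes higher and 365 lower, and limma voom with sample quality weights called 190 higher and 372 lower, with 417 genes called by both tools in the same direction. In 380 genes all CD43-KO values lay above all Vec values and in 639 genes all lay below, together 5.59% of the genes against 1.59% by chance. Both chance values are averages, and counts by chance can lie far from them. Other splits of the 9 tumours into 4 and 5 gave up to 3237 genes with an unadjusted edgeR p under 0.05. The split with 3237 set CD43-KO replicates 1, 2, 3 and 5 against all Vec tumours and CD43-KO replicate 4. It kept most of the real grouping, so its count is not one of chance alone. The share without overlap was not computed for other splits. Leaving out Vec replicate 3 gave 8 higher and 21 lower genes with edgeR, leaving out Vec replicate 2 gave 1 higher and leaving out CD43-KO replicate 2 gave 1 lower.

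The genes with the smallest edgeR p separated the groups without overlap, although none passed. They were picked by p from the same 9 tumours, so the lack of overlap is no separate support. Unc13d, a priming factor for the release of cytotoxic granules, was at 21.4 ± 1.14 CPM in Vec and 34.0 ± 1.69 CPM in CD43-KO tumours (log2 fold change 0.67 ± 0.08 SE, edgeR adjusted p = 0.0706). Slc11a2, an iron transporter, was at 44.9 ± 3.42 and 61.7 ± 1.49 CPM. The glycerol kinase gene Gk was at 19.9 ± 1.27 and 29.8 ± 2.45 CPM, and Ddx21, which encodes an RNA helicase of the nucleolus, at 140 ± 7.44 and 188 ± 9.56 CPM. Their log2 fold changes were 0.46, 0.58 and 0.43, with edgeR adjusted p from 0.125 to 0.135. Zfp993, a zinc finger gene, was at 0.10 ± 0.05 and 1.04 ± 0.50 CPM (3.31 ± 0.48 log2, edgeR adjusted p = 0.103). Whether its reads are shared with similar zinc finger genes was not tested. On the lower side, Aldh3a1, an aldehyde dehydrogenase, was at 33.9 ± 7.38 CPM in Vec and 9.87 ± 2.68 CPM in CD43-KO tumours (-1.78 ± 0.22 log2, edgeR adjusted p = 0.0706). Crabp1, a binding protein of retinoic acid, was at 106 ± 34.2 and 28.4 ± 8.97 CPM, and Medag at 84.8 ± 22.5 and 37.1 ± 2.75 CPM. The transcription factor gene Osr1 was at 38.3 ± 3.05 and 23.03 ± 2.62 CPM, and Cdc42ep2, which encodes an effector of the GTPase Cdc42, at 52.1 ± 12.2 and 24.4 ± 3.82 CPM. The log2 fold changes of Crabp1, Medag, Osr1 and Cdc42ep2 were -1.90, -1.19, -0.73 and -1.10, with edgeR adjusted p from 0.103 to 0.125. DESeq2, run on the same counts, called all 10 of these genes.

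**Figure D2:**
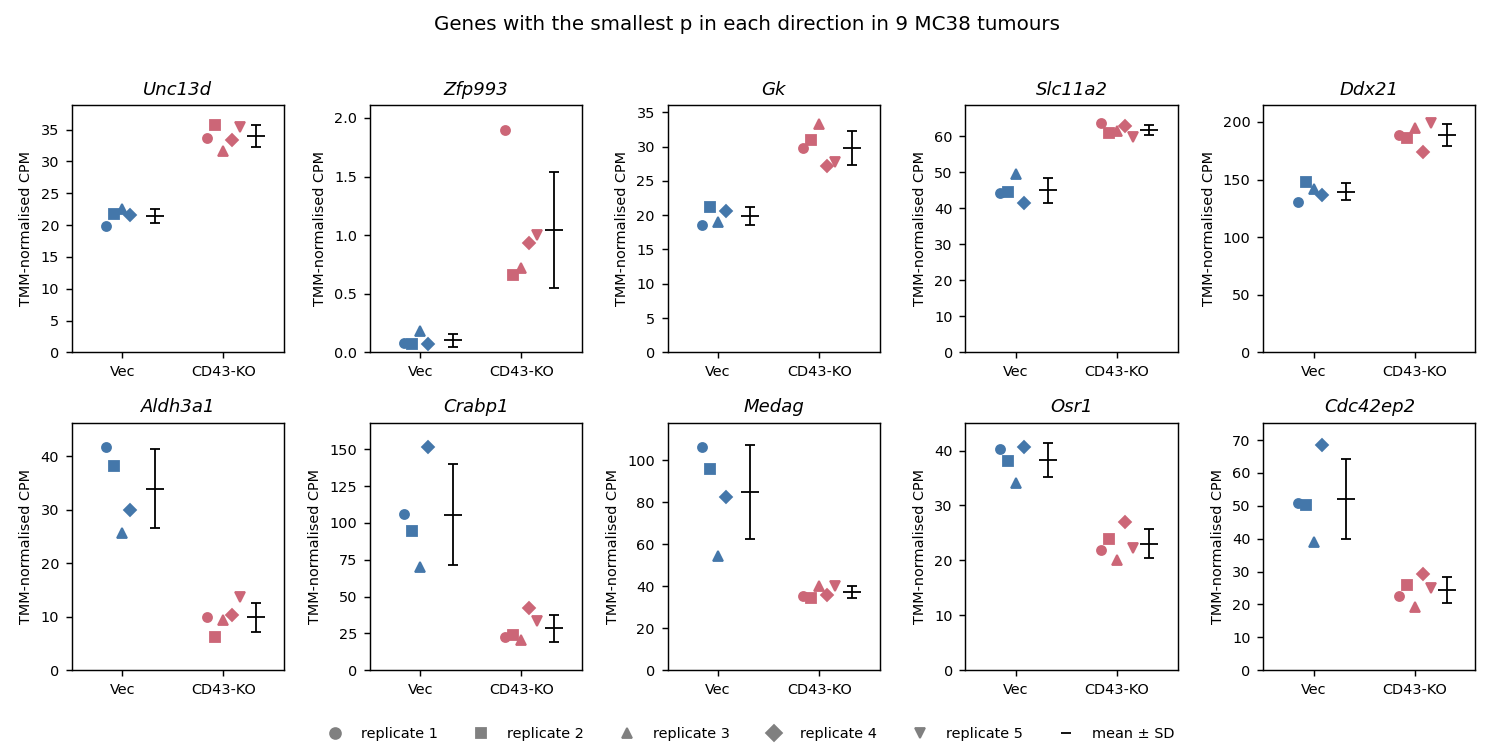
Levels of the 10 genes with the smallest edgeR p (y axis, TMM-normalised CPM) in 4 Vec and 5 CD43-KO tumours, with a marker for each replicate and the group mean ± SD in black. The upper row holds the genes with higher CD43-KO levels and the lower row those with lower levels, and the groups did not overlap for any of them.

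The largest DESeq2 changes without overlap were chosen after the values were seen. The higher ones included Csf3r, the receptor of granulocyte colony-stimulating factor (4.15 ± 0.55 CPM in Vec and 11.4 ± 6.08 CPM in CD43-KO tumours), Mefv, which encodes pyrin (3.30 ± 0.57 and 8.57 ± 4.57 CPM), the chemokine gene Ccl4 (5.15 ± 1.11 and 13.0 ± 7.70 CPM) and Tnfsf14, a TNF family ligand (1.84 ± 0.40 and 4.40 ± 1.29 CPM). Their DESeq2 log2 fold changes were 1.45, 1.37, 1.32 and 1.25. Tfrc, the transferrin receptor, was at 58.0 ± 21.3 and 127 ± 34.0 CPM (DESeq2 log2 fold change 1.12). The others were Zfp600 (2.24, uncertain because of copies), Phlda2 (1.62), Gpc6 (1.20), Clmn (1.16) and Sorl1 (1.12). The lower ones, beside Crabp1, Aldh3a1 and Medag, were the tight junction gene Cldn1 (DESeq2 log2 fold change -1.28), the protease inhibitor gene Cst6 (-1.14), Calr4 (-1.47), Pllp (-1.27), Mrgprf (-1.22), Ip6k3 (-1.16) and Chtf8 (-1.41). Chtf8 was at 203 ± 21.1 CPM in Vec tumours and at 178 CPM in CD43-KO replicate 2, against 38.4 to 56.96 CPM in the other CD43-KO tumours. The DESeq2 count of 612 depended on single tumours. It was 195, 283 and 272 without Vec replicates 1, 2 and 4, and 210 and 227 without CD43-KO replicates 1 and 2, but 1101 without Vec replicate 3 and 1204 and 1180 without CD43-KO replicates 3 and 4. The excess of lower genes was also not stable, with 681 higher and 499 lower genes without CD43-KO replicate 4 and 241 and 228 without CD43-KO replicate 5.

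Lymphocyte lists were higher in CD43-KO tumours by camera with the preset correlation, and 3 of the 5 tumours lay above every Vec tumour in most of them. All 18 measured members of the T cell list had a log2 fold change above 0, with a median of 1.09, and the score difference was 0.86 log2 (SD 0.98 in CD43-KO and 0.27 in Vec). The scores of CD43-KO replicates 1, 2 and 3 were 0.86, 1.64 and 1.98, above every Vec tumour, and that of CD43-KO replicate 4 was -0.41, below every Vec tumour. Camera gave an adjusted p of 9.0e-05 with the preset correlation and an adjusted p of 0.712 with an estimated correlation, and the exact permutation p of the scores was 0.167. The most abundant T cell members were Lck, a kinase of T cell receptor signalling (8.63 ± 1.72 and 12.7 ± 6.52 CPM, uncertain because of a copy name), and Cd3d, a chain of the receptor complex (5.27 ± 1.24 and 11.4 ± 8.91 CPM). The CD8 and cytotoxic effector list had 18 of 18 members above 0 and a score difference of 0.76 (camera adjusted p = 0.00113, and adjusted p = 0.724 with an estimated correlation). Its chemokine gene Ccl5 was at 16.4 ± 6.25 and 59.3 ± 56.96 CPM. The regulatory T cell list had 10 of 10 members above 0 and a score difference of 0.75 (camera adjusted p = 0.000274, and adjusted p = 0.668 with an estimated correlation). In it, Ikzf2 and Tnfrsf18 passed when adjusted over the list alone, and Tnfrsf9, an uncertain gene with a copy name, was the most abundant at 40.2 ± 6.37 and 51.7 ± 12.2 CPM. The list of T cell inhibitory receptors and ligands differed by 0.62 and the natural killer list by 0.60, with camera adjusted p of 0.00207 and 0.0321, and adjusted p of 0.712 and 0.724 with an estimated correlation. Within them, Lgals9 was at 70.1 ± 15.7 and 57.6 ± 8.06 CPM, Vsir at 39.3 ± 3.36 and 52.2 ± 18.8 CPM, Klra4 (uncertain) at 108 ± 30.4 and 103 ± 22.5 CPM, and Il2rb at 13.7 ± 2.54 and 29.2 ± 19.02 CPM.

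The B and plasma cell list had 8 of 11 measured members above 0 and a score difference of 0.93 (camera adjusted p = 0.00567, and adjusted p = 0.668 with an estimated correlation). Jchain, which joins the units of polymeric antibodies, was at 6.36 ± 5.26 CPM in Vec and 25.9 ± 19.6 CPM in CD43-KO tumours, and Cd22 and Cd79a passed when adjusted over the list alone. The second most abundant member, Igkc, was not higher, with means of 6.30 ± 6.73 and 6.06 ± 12.1 CPM. It was at 27.8 CPM in CD43-KO replicate 1 and between 0.290 and 1.07 CPM in the other CD43-KO tumours, against 0.758, 9.98, 13.94 and 0.536 CPM in Vec replicates 1 to 4. Without CD43-KO replicate 3, the tumour with high muscle and fat transcripts described below, the call of the CD8 and cytotoxic effector list was lost (camera adjusted p = 0.0550, score difference 0.41) and the T cell call was kept (0.00808, score difference 0.58). Without it the inhibitory list differed by 0.39 (0.0449) and the natural killer list by 0.34. The B and plasma cell call was lost with the stricter filter (0.388), at a difference of 0.98. With the score of 4 Y-linked genes as a covariate, an alternative chosen after the data were seen, none of these 6 lymphocyte lists was called (camera adjusted p from 0.092 to 0.693). The T cell difference was then 0.12, and those of the CD8 and natural killer lists turned to -0.12 and -0.035. The Y-linked score followed the leukocyte gene Ptprc over the 9 tumours, an observed relation. This covariate thus overlaps with leukocyte content and is no separate test of leukocyte lists. The natural killer call was lost without Vec replicate 2 or 4 or CD43-KO replicate 2 or 3, with camera adjusted p from 0.0633 to 0.265.

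Myeloid lists were also higher, among them the neutrophil and granulocytic list (score difference 0.59, camera adjusted p = 0.00149, and adjusted p = 0.668 with an estimated correlation). Of its 16 measured members 12 lay above 0 and 4 below, among the latter S100a8 (18.4 ± 14.05 and 15.6 ± 15.3 CPM) and S100a9 (18.3 ± 15.2 and 13.96 ± 14.9 CPM), which encode the subunits of calprotectin, a main protein of neutrophils. Adjusted over the list alone, 6 members passed, all higher, against 0 over all genes tested, and DESeq2 called 5. Without Vec replicate 2 the score difference of the list was 0.33 (camera adjusted p = 0.0398). These 6 were Csf3r, Trem1, Il1r2, Clec4e, Ltf and Arg2. Trem1, an amplifier of myeloid inflammation, was at 5.80 ± 0.47 and 8.71 ± 0.88 CPM, and Clec4e, a receptor for microbial glycolipids, at 18.1 ± 2.601 and 36.5 ± 18.7 CPM. The most abundant member, Clec4d, was at 29.1 ± 8.46 and 64.7 ± 44.1 CPM. In the inflammatory macrophage list all 12 measured members lay above 0 (score difference 0.69, camera adjusted p = 0.00035, and adjusted p = 0.712 with an estimated correlation). Nos2, Il1b and Ptgs2 passed when adjusted over the list alone. Nos2, the inducible nitric oxide synthase, was at 34.3 ± 7.28 and 67.9 ± 26.7 CPM, and Il1b at 15.05 ± 4.95 and 47.8 ± 29.3 CPM. The interferon-induced chemokine genes Cxcl9 and Cxcl10 were at 190 ± 39.8 and 299 ± 151 CPM and at 108 ± 24.4 and 143 ± 49.8 CPM. The macrophage and monocyte list differed by 0.43 and the dendritic cell list by 0.46, with camera adjusted p of 0.0027 and 0.0207, and adjusted p of 0.712 for both with an estimated correlation. Lyz2 was at 2433 ± 781 and 4139 ± 2142 CPM, Apoe at 769 ± 150 and 1274 ± 788 CPM, Fscn1 at 249 ± 36.4 and 225 ± 46.4 CPM and Irf8 at 53.7 ± 6.83 and 76.1 ± 31.7 CPM. Without CD43-KO replicate 3, the tumour with muscle and fat transcripts, both calls were lost (camera adjusted p = 0.0793 and 0.131, score differences 0.23 and 0.29). With the Y-linked covariate the neutrophil call was kept (0.48, camera adjusted p = 0.0244) and those of inflammatory macrophages, macrophages and dendritic cells were lost (0.127, 0.838 and 0.849), with differences of 0.27, -0.0073 and 0.02. The dendritic cell call was lost also without Vec replicate 1 (0.0596) or CD43-KO replicate 2 (0.0732).

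The lists of chemokines, MHC class II presentation, the interferon gamma response and CD43 ligands and partners differed by 0.54, 0.40, 0.26 and 0.36 log2. Their camera adjusted p were 0.0027, 0.0369, 0.0234 and 0.0365, and with an estimated correlation the adjusted p were 0.712, 0.790, 0.790 and 0.668. Among chemokines Ccl6 was at 332 ± 128 and 709 ± 548.15 CPM and Ccl2, which attracts monocytes, at 195 ± 31.5 and 303 ± 122 CPM. In the MHC class II list all 11 measured members lay above 0, with Cd74, the invariant chain, at 832 ± 148 and 1145 ± 508 CPM and Ctss, a protease that trims it, at 395 ± 112 and 1020 ± 883 CPM. Gbp2 and Irf1 of the interferon gamma list were at 476 ± 104 and 600 ± 211 CPM and at 246 ± 29.1 and 303 ± 82.2 CPM. The CD43 ligand list had a score above every Vec tumour in all 5 CD43-KO tumours (exact permutation p = 0.0397, adjusted over 32 lists 0.381). Its most abundant members, the galectin genes Lgals1 and Lgals3, were at 3071 ± 580 and 2954 ± 762 CPM and at 1105 ± 174 and 1170 ± 253 CPM, while Sele, which encodes E-selectin, passed when adjusted over the list alone (0.17 ± 0.07 and 0.66 ± 0.31 CPM). Without CD43-KO replicate 3 the calls of all 4 lists were lost, with camera adjusted p of 0.131, 0.401, 0.467 and 0.0856 and score differences of 0.25, 0.18, 0.08 and 0.31. With the Y-linked covariate the 4 calls were also lost (0.949, 0.483, 0.171 and 0.127), the MHC class II and interferon gamma differences turning to -0.09 and -0.10, and with the stricter filter those of MHC class II and CD43 ligands (0.0642 and 0.115). Without CD43-KO replicate 4 the MHC class II difference was 0.60. The MHC class II call was lost also without Vec replicate 1, 2 or 3 or CD43-KO replicate 2 (0.0590 to 0.184), the interferon gamma call without Vec replicate 1 or 2 (0.131 and 0.0720), and the CD43 ligand call without Vec replicate 1 or 2 or CD43-KO replicate 1 or 2 (0.0502 to 0.102).

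Lists of hypoxia and glycolysis and of the type I interferon response were lower in CD43-KO tumours. The hypoxia and glycolysis score was lower by -0.35 log2, below every Vec tumour in all 5 CD43-KO tumours (exact permutation p = 0.0317, adjusted over 32 lists 0.381). The margin was narrow, with CD43-KO replicate 5 at -0.159 and Vec replicate 3 at -0.153. Camera gave an adjusted p of 0.00035, and an adjusted p of 0.712 with an estimated correlation. Of its 20 members 17 lay below 0, and 5 lower and 1 higher passed when adjusted over the list alone, against 0 over all genes tested. The 5 were Ddit4, an inhibitor of mTORC1 induced by stress (153 ± 42.5 and 82.0 ± 19.7 CPM), Adm, which encodes adrenomedullin, P4ha1, a collagen prolyl hydroxylase (263 ± 24.0 and 183 ± 37.1 CPM), Ankrd37 and the aldolase gene Aldoa (1701 ± 400 and 1218 ± 77.2 CPM). Hk2, a hexokinase, was the 1 that was higher (62.7 ± 4.002 and 80.8 ± 13.2 CPM). The most abundant members, Gapdh and Ldha, were at 2634 ± 584 and 2246 ± 186 CPM and at 2562 ± 459 and 2048 ± 135 CPM. In the type I interferon list 20 of 21 members lay below 0, with a score difference of -0.41 (camera adjusted p = 1.9e-05, and adjusted p = 0.668 with an estimated correlation). The scores were below every Vec tumour in 3 of 5 CD43-KO tumours (exact permutation p = 0.0476, adjusted over 32 lists 0.381). DESeq2 called the antiviral genes Ifit3 (44.6 ± 11.9 and 23.4 ± 8.93 CPM) and Isg15 (59.1 ± 16.9 and 39.2 ± 4.25 CPM), and the most abundant members, Bst2 and Stat2, were at 274 ± 47.6 and 253 ± 43.4 CPM and at 56.7 ± 1.58 and 54.6 ± 5.74 CPM. Both lower calls were kept without each of the 9 tumours. With the Y-linked covariate the hypoxia and glycolysis call was lost (-0.13, camera adjusted p = 0.171), and the type I interferon call was kept at a smaller difference (-0.21, camera adjusted p = 0.0244).

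**Figure D3:**
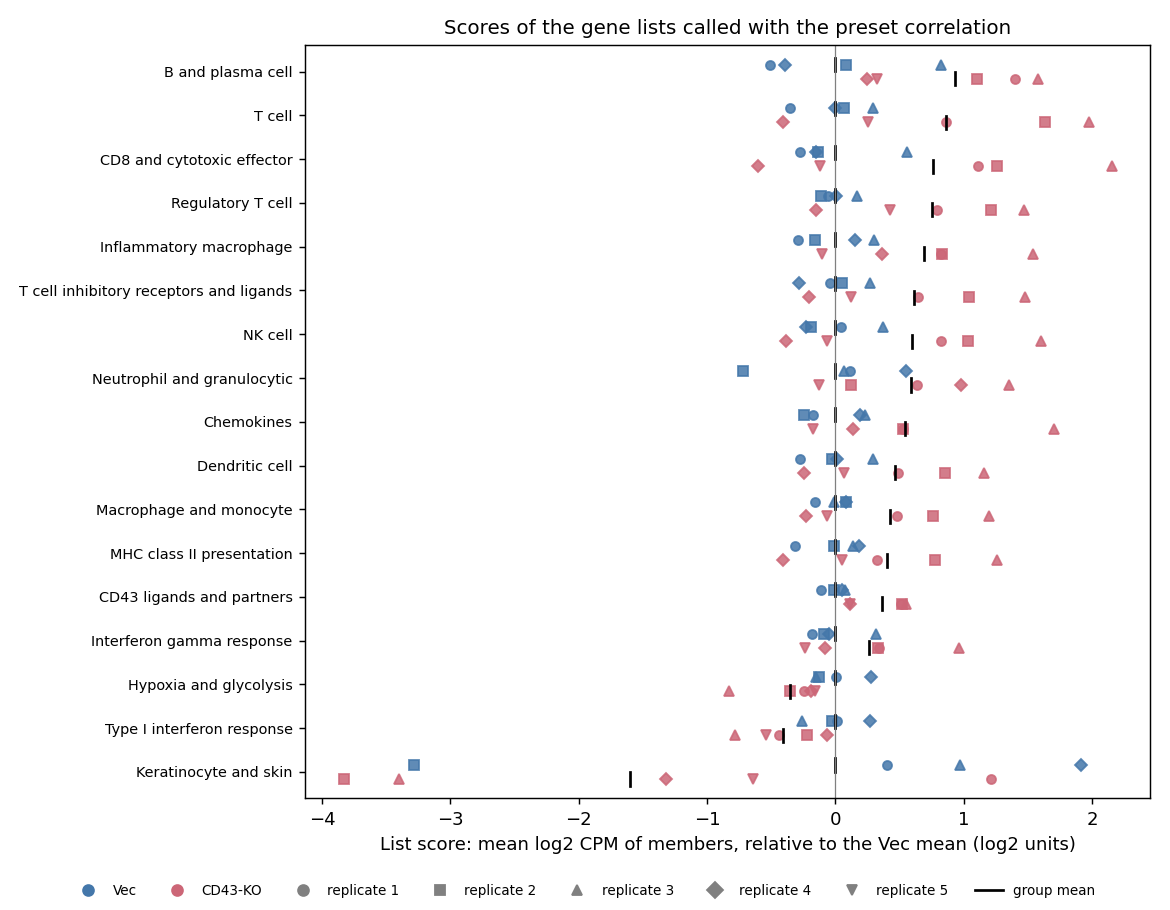
Scores of the 17 gene lists called by camera with the preset correlation (x axis, mean log2 CPM of the members relative to the Vec mean), with Vec tumours in blue, CD43-KO tumours in red, a marker for each replicate and black bars at the group means. CD43-KO replicates 1, 2 and 3 had the highest T cell scores, at 0.86, 1.64 and 1.98, and CD43-KO replicate 4 the lowest, at -0.41.

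In all, camera with the preset correlation called 14 of 32 lists higher and 3 lower, and 0 with an estimated correlation (smallest adjusted p = 0.668). By fry 0 lists passed for a change in 1 direction (smallest adjusted p = 0.107) and 1, the neutrophil list, for change in either direction. The exact permutation p of the scores was 0.0397, 0.0317 and 0.0476 for the CD43 ligand, hypoxia and type I interferon lists and ranged from 0.0635 to 0.349 for the other 14 lists called, and none passed when adjusted over the 32 lists (smallest 0.381). Without CD43-KO replicate 3 camera called 10 lists. Markers of other tissues varied between single tumours. CD43-KO replicate 3 had scores of 3.23 for skeletal muscle, 3.32 for adipocytes and 1.64 for peripheral nerve and glia, with Acta1 at 347 CPM against 24.6 to 39.0 CPM in the other CD43-KO tumours and Cfd at 350 CPM against 2.48 to 6.65 CPM. This tumour also had the highest T cell, macrophage and neutrophil scores of the 9 tumours. The third list called lower, keratinocyte and skin, had scores from -3.83 to 1.91, with score SDs of 2.07 in CD43-KO and 2.28 in Vec tumours, and differed by -1.60 (camera adjusted p = 0.00834, and adjusted p = 0.724 with an estimated correlation). Its most abundant members were Krt14 (485 ± 135 and 384 ± 67.0 CPM) and Sfn (30.0 ± 16.4 and 17.6 ± 10.4 CPM). The member Krt5 was at 0.09 CPM in Vec replicate 2 and at 0 CPM in CD43-KO replicates 2 and 3. Krt14 was at 337, 356 and 291 CPM in these tumours, so its level cannot be read as skin tissue alone. The call was lost without Vec replicate 3 or 4 or CD43-KO replicate 2 or 3 (0.0732 to 0.154). It was lost also with limma voom (-1.77, camera adjusted p = 0.778) and with the Y-linked covariate (-0.74, camera adjusted p = 0.256). The score difference was -0.97 without Vec replicate 4, -1.04 without CD43-KO replicate 2 and -2.63 without Vec replicate 2.

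The other 15 measured lists were not called. Score differences were 0.45 for alternatively activated macrophages and -0.07 for oxidative phosphorylation (camera adjusted p = 0.0619 for both), -0.70 for epithelial genes (0.104), -0.09 for mesenchymal transition (0.154), 0.52 for skeletal muscle (0.249) and 0.20 for the NF-kB and TNF response (0.290). For fibroblasts and matrix the difference was -0.02 (camera adjusted p = 0.449), for peripheral nerve and glia 0.31 and for endothelial cells 0.12 (0.509 for both). Cell cycle genes differed by 0.03, Wnt target genes by 0.10, adipocyte genes by -0.28 and immediate early genes by -0.04 (camera adjusted p = 0.519 for these 4). MHC class I presentation differed by 0.06 and erythroid genes by -0.20 (0.527 for both). Several of these differences rested on single tumours. Without CD43-KO replicate 3 those of alternatively activated macrophages, skeletal muscle and peripheral nerve turned to -0.02, -0.16 and -0.02, and the erythroid difference ranged from -0.54 to 0.11 and the adipocyte difference from -1.19 to 0.06 over the 9 tumours left out in turn. Leaving out 1 tumour gave some of these lists a call. The adipocyte difference was -1.19 without CD43-KO replicate 3 (camera adjusted p = 0.000148), the tumour with high fat transcripts. Alternatively activated macrophages were called without Vec replicate 3 or 4 or CD43-KO replicate 4 or 5 (differences 0.56, 0.45, 0.73 and 0.63), and oxidative phosphorylation without Vec replicate 1 or 2 or CD43-KO replicate 3 (-0.12, -0.11 and -0.14). Epithelial genes were called without Vec replicate 2 (-1.19), skeletal muscle without CD43-KO replicate 1 (0.76), endothelial cells without CD43-KO replicate 4 (0.29) and the NF-kB and TNF response without CD43-KO replicate 5 (0.31). Members of uncalled lists passed when adjusted over the list alone, namely Vim, Snai1, Twist2 and Mmp2 of the mesenchymal list and Col6a1 and Col6a2 of the fibroblast list, Ndufv1 of oxidative phosphorylation, Apcdd1 of the Wnt targets and Pmp22 of peripheral nerve, all lower, and Nr4a1 of the immediate early list, higher. Vim, which encodes vimentin, was at 4234 ± 497 and 3225 ± 394 CPM, and Col6a1 at 490 ± 123 and 309 ± 46.6 CPM. In some lists the median of the fitted log2 fold changes, the mean score and the camera direction differed in sign. The adipocyte median was 1.58 while its score difference and camera direction were lower, the fibroblast median was 0.002 with a lower score, and the immediate early list had a median of 0.03 and a higher camera direction with a lower score.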

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

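The tests chosen only after the result was seen were those on muscle and fat tissue, on loss of CD43 and all 3 on Spn, together with the set of 9 leukocyte lists and the splits for genes past the threshold. The tests on copies of chromosome 19 and on the share of host cells behind its shift were set before the result was seen but used in a form changed after it. Conditions added after the results were known moved both, and the test of host leukocytes for Spn, to an open outcome. By their earlier forms, the copies would have been read as met, and host cells would have been argued against for both patterns.

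In 31 of 262 tests of a group of 4 or 5 tumours, the highest or lowest tumour lay far from the others of its group, where chance gives about 1 in 20 (13.1). CD43-KO replicate 3 gave 16 of them, Vec replicate 3 gave 6, Vec replicate 4 gave 4, CD43-KO replicate 1 gave 3, and CD43-KO replicates 2 and 5 gave 1 each. In CD43-KO replicate 3 the scores were 3.23 for skeletal muscle, 3.32 for adipocytes and 0.19 for oxidative phosphorylation. Genes of other tissues in it were Acta1 at 347.2 CPM, Fabp4 at 260.8 CPM and Cfd at 349.7 CPM. Immune genes in it were Ifng at 11.45 CPM, Ccl4 at 26.43 CPM, Ccl6 at 1664 CPM, Ccl2 at 516.9 CPM, Arg1 at 1476 CPM and B2m at 2627 CPM. Other genes in it were Tfrc at 186 CPM, Pcna at 507.7 CPM, Cox4i1 at 804.6 CPM and Lgals3 at 1619 CPM.

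In Vec replicate 3 the CD8 and cytotoxic effector score was 0.56, and Zfp993 was at 0.183 CPM, Spp1 at 750.9 CPM, Ctss at 560.9 CPM, Ccl6 at 522.7 CPM and Sox9 at 181.8 CPM. In Vec replicate 4 Gpc6 was at 0.8499 CPM, Pllp at 3.547 CPM, Atp5b at 1264 CPM and Cox4i1 at 893.7 CPM. In CD43-KO replicate 1 the epithelial score was 0.17, Zfp993 was at 1.895 CPM and Igkc at 27.77 CPM. Chtf8 was at 177.6 CPM in CD43-KO replicate 2, against 38.4 to 56.96 CPM in the other CD43-KO tumours. Calr4 was at 1.132 CPM in CD43-KO replicate 5.

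All 9 leukocyte lists (T, CD8, natural killer, regulatory T, B and plasma, macrophage, inflammatory macrophage, neutrophil and dendritic cell) were called higher in CD43-KO tumours by camera with the preset correlation, and none with an estimated correlation (adjusted p from 0.668 to 0.724). Without CD43-KO replicate 3, the tumour with muscle and fat transcripts, 5 of the 9 were still called with the preset correlation. Their score differences were then 0.40 to 0.76, so they did not rest on that tumour alone. These 5 were picked by that outcome, so it cannot decide on muscle and fat tissue as a cause. The other 4 were the CD8, natural killer, macrophage and dendritic cell lists, whose differences were 0.41, 0.34, 0.23 and 0.29 without that tumour. That of the CD8 list was no smaller than that of the neutrophil list, which kept its call at 0.40. For these, muscle and fat tissue cannot be told apart from the loss of 1 tumour from the test. More host cells of every kind is not decided. The T cell score minus the mean of the endothelial and fibroblast scores was higher by 0.81 log2 (SD 0.68 in CD43-KO, 0.29 in Vec). This goes against an equal rise of these cells, but its exact permutation p of 0.0556 missed the threshold. The endothelial and fibroblast scores themselves differed by 0.12 and -0.02 log2. With the score of 4 Y-linked genes as a covariate, the T cell difference went from 0.86 to 0.12 log2. As that score followed the leukocyte gene Ptprc, this cannot tell leukocytes from host cells of every kind. Loss of CD43 in the implanted cells stays open. The camera adjusted p of the T cell list was 0.712 with an estimated correlation, and 1 CD43-KO tumour lay below every Vec tumour. A clearer difference would also not have told loss of CD43 from any other difference between the knockout and vector cells.

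The 568 chromosome 19 genes tested had a median log2 fold change that lay at -0.13 from that of all genes, against -0.03 to 0.04 for the other autosomes, and the 5 CD43-KO libraries lay at -0.22 to -0.05, below every Vec library at -0.03 to 0.03 (exact permutation p = 0.0159, adjusted over 20 chromosomes 0.317). GC content and gene length are argued against as the whole cause, as -0.13 ± 0.015 (SE from a bootstrap over genes) was left after a fit on them and on level, for the 91.7% of these genes with a GC value. A different share of host cells cannot be told apart, since the shift between libraries of -0.13 ± 0.034 (SE over tumours) went to -0.084 ± 0.022 (SE over tumours) with the score of 4 Y-linked genes as a covariate, and in the fit of genes with it chromosome 15 lay at 0.09, further than chromosome 19 at -0.086. Fewer copies of chromosome 19 in the CD43-KO line could give a shift of the whole chromosome, and the smaller shift of its 2 parts was -0.13. This stays open, because CD43-KO replicate 3, with the highest Y-linked score, had the largest shift, the opposite of dilution by host cells.

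Spn was lower in CD43-KO tumours but present at 6.81 CPM or more. The mean of log2 Spn minus log2 Ptprc was -0.038 in Vec and -1.92 in CD43-KO tumours, without overlap between the groups. A swap of labels between the groups is argued against, as the lowest Vec library lay 7.43 CPM above the highest CD43-KO library. Host leukocytes as the only source of Spn in CD43-KO tumours cannot be told apart from other sources: the SD of log2 Spn minus log2 Ptprc over these tumours was 0.93, or 2.26 times the highest such SD of 10 leukocyte genes (0.41), but an SD of 5 values is imprecise and the Spn level of each leukocyte type was not measured. The ratio did not follow the neutrophil score in each tumour: CD43-KO replicates 4 and 5, with its highest and lowest value, had neutrophil scores of 0.98 and -0.13, while CD43-KO replicate 3 had the highest neutrophil score, 1.35, and the second lowest ratio, -2.25. Tumour cells that kept Spn transcripts may add to the lowest level of 6.81 CPM, which gene counts cannot show.

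Splits of the 9 tumours into 4 and 5 were drawn, and the numbers of splits here include the real one. For the 0 genes past the threshold with edgeR they test nothing, since each of the 100 splits has at least 0 (highest other 18). Chance could not be excluded for the other 3 counts, but some of the splits keep most of the real grouping. The split that gave 3237 genes set CD43-KO replicates 1, 2, 3 and 5 against the rest. Another, with 2940 genes, set CD43-KO replicates 1, 2, 4 and 5 against the rest. A real difference between the groups would also raise the counts of such splits. The 2806 genes with an unadjusted p under 0.05 were reached by 5 of 100 splits (highest other 3237), the 612 DESeq2 calls by 3 of 40 (highest other 1107, with Vec replicates 1, 2 and 4 and CD43-KO replicate 4 in the smaller group) and the 17 lists called by 44 of 100 (highest other 24).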

How the results depend on the processing

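The fits with a covariate, those without names with a copy suffix and the alternatives for the DESeq2 count were chosen after seeing the data. The edgeR count of 0 genes became 1 with no filter, 612 with DESeq2 and 562 with limma voom, and ranged from 0 to 29 when each tumour was left out. The count of 17 lists became 0 with an estimated correlation and 3 (1 higher, 2 lower) with the Y-linked covariate, and it ranged from 10 to 19 when each tumour was left out. The DESeq2 count of 612 ranged from 195 to 1204 when each tumour was left out and was 573 without copy names. With the Y-linked covariate 15 of the 17 calls were lost, those of the neutrophil and type I interferon lists were kept, and the adipocyte list was gained (-1.58, adjusted p = 0.00333). The score difference then changed sign for the lists of CD8 and cytotoxic effectors (-0.12), natural killer cells (-0.035), macrophages and monocytes (-0.0073), MHC class II (-0.089) and the interferon gamma response (-0.10). The Y-linked score follows the leukocyte gene Ptprc, so it takes out leukocyte content by construction and is no test of leukocyte lists. The stricter filter ended the calls of the B and plasma cell, MHC class II and CD43 ligand lists, and limma voom that of the keratinocyte list. Calls were gained for alternatively activated macrophages with no filter and with DESeq2, for oxidative phosphorylation and skeletal muscle with DESeq2, which called 20 lists in all, and for adipocytes with limma voom. The cause of the other changes was not tested. Spn kept its direction and missed the threshold in 20 of 20 alternatives, at -1.20 to -0.69 log2 and an adjusted p from 0.0982 to 1. Of 676 values of named genes under alternatives, 612 kept their side of the threshold, 2 of these with the other sign, and 64 passed it. Of 640 values of lists, 559 kept their side of the threshold, 23 of these with the other sign, 58 were no longer called, 18 became called and 5 called ones changed sign. Estimation without the robust option does not apply to camera, and pseudocounts for normalized values do not apply to counts.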

Other observations

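The gene families and genes here were chosen after the values were seen, and an adjustment over the 7 families does not cover that choice. Immunoglobulin variable genes had a score higher by 3.01 log2 in CD43-KO tumours (8 genes, exact permutation p = 0.0238, adjusted over 7 families 0.0833), and Igha, the heavy chain of IgA, was at 13.1 ± 10.8 CPM in Vec and 59.1 ± 32.2 CPM in CD43-KO tumours. T cell receptor variable genes differed by 1.10 (9 genes, exact permutation p = 0.151). Structural RNAs were lower by -2.88 log2 (5 genes, exact permutation p = 0.0159, adjusted 0.0833), with Rn7s1 at 105 and 130 CPM in Vec replicates 1 and 3, at 8.57 and 32.4 CPM in Vec replicates 2 and 4, and at 6.57 ± 2.09 CPM in CD43-KO tumours. Ribosomal protein genes differed by -0.31 (84 genes, exact permutation p = 0.0952), and DESeq2 called 19 of them lower. Histone genes differed by -0.57, Y-linked genes by 0.61 and olfactory genes by 0.39.

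Over the 9 tumours, the level of the leukocyte gene Ptprc and the score of 4 Y-linked genes had a Pearson r of 0.973 (exact permutation p = 1.1e-05) and a Spearman rho of 0.967 (exact permutation p = 0.000165). Without the 2 tumours farthest from the median of Ptprc, CD43-KO replicates 2 and 3, r was 0.983, and this was the 1 relation computed. Ddx3y was at 10.1 ± 2.06 CPM in Vec and 18.4 ± 11.01 CPM in CD43-KO tumours, Ddx3x at 391 ± 57.1 and 465 ± 36.4 CPM, and Xist at 0 to 0.397 CPM. Chil3, a chitinase-like gene of macrophages, was at 989 CPM in CD43-KO replicate 3 and at 5.43 to 44.2 CPM in the other 8 tumours.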
